A study of Homo sapiens with 4 samples.

How the data were processed

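Gene expression was measured on Affymetrix arrays in 4 samples of total RNA, 2 of NCI-H1299 cells and 2 of NCI-H1299/CDDP cells. The cells were grown in RPMI medium with fetal bovine serum and collected near full density, and RNA was extracted with Trizol and converted to biotin-labelled single-stranded cDNA, per the labels' protocols. The titles call both samples of a group biological replicates, but no label says whether they came from separately grown or separately selected cultures. The p-values therefore measure the spread between these samples, which may be partly technical.

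The authors deposited 1 table of values with 138745 rows and 1 column per array. The deposited values are on a log2 scale, judged from their range of 0.43 to 14.08 and from background rows that rise with the GC content of the probe. The submitters' processing notes name Affymetrix Expression Console, MAS5, RMA and PLIER, with no version and no role, so which method summarised and normalized the probes is not given in the sources used here. The medians of the 4 columns lay between 4.66 and 4.70, so the arrays had been put on a common scale, and genes had not been centred. Scanner files and detection calls were not used here.

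Rows were named through a table that pairs probes with the platform annotation, and names were updated through a RefSeq gene table of the GRCh38.p14 assembly. Exactly 1 gene was named by 36176 rows, several genes by 1119 rows and none by 98610 rows, and 2840 rows were array controls. Of the rows naming 1 gene, 25516 were matched by gene identifier, 9899 by symbol and 623 by an older symbol, and 138 kept the name in the table. They held 33458 distinct genes, of which 1707 had more than 1 row. The row with the highest mean over the 4 arrays represented such a gene. Genes with a mean below the 25th percentile of all rows, a log2 value of 3.47, were left out, which left 28565 tested genes, 16357 of them protein-coding. Genes without a row naming them alone were not analysed here. The build used to design the array is not stated, so no coordinates are printed, and the assembly served only for names and for which genes neighbour each other.

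No further normalization was applied. Differences are NCI-H1299/CDDP minus NCI-H1299 on the log2 scale, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05, and the standard errors given are the moderated ones. The fit had 2 residual and 4.84 prior degrees of freedom. The number of arrays limits the precision. As a measure of background, the 95th percentile of the 612 negative control rows was between 4.89 and 5.11, and 70.9% to 74.9% of the tested genes lay above it on an array. A group was said to lie in the negative-control range when both of its arrays were at or under that percentile. Background shrinks a difference when a group lies there, and no fold is given for such genes.

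The groups were tested on 36 gene lists with 844 tested members. They were fixed, like the designs, before the data were examined. camera of limma was run with a preset inter-gene correlation of 0.01 and, as an alternative, with an estimated correlation, and fry was run beside it. The camera p-values were adjusted over the 36 lists. Members were also adjusted over the list alone. The text names the 12 genes with the largest positive and the 12 with the largest negative difference among called protein-coding genes with established names whose arrays separated by group. It also names up to 4 called members of each list with the largest absolute difference, or 2 with the smallest p where none was called, and 24 genes of cisplatin response and cell state whatever their result. Of these, 2 of the 24 genes and 1 of the 36 lists, which camera called higher, are not reported here. Other genes named in the closing section, and the further members of a list named beside them, were chosen after their values were seen.

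For regional shifts, 28332 tested genes were put in chromosomal order, leaving out the Y chromosome. The median difference in windows of 50 neighbouring genes, centred on the median of all ordered genes, was set against the largest absolute window median in each of 10000 shuffles of the gene order, with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0. Figures were drawn with matplotlib 3.10.9.

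The steps were tested on simulated data in which genes varied independently of each other. For limma and camera the simulated genes had the real genes' mean levels and variances drawn from the fitted prior. For the window scan all genes had the same spread. Among 28565 simulated genes compared between 2 and 2 arrays, the limma fit found 0 of 50 genes changed by 0.5 on the log2 scale, 3 of 50 changed by 1, 45 of 50 changed by 2 and 50 of 50 changed by 3. It made 3 false calls among 101. Genes changed by 1 or less were thus mostly missed in this simulation. The data gave 1011 calls, and fewer changed genes make the adjustment stricter, so these rates do not carry over to the data. In the same simulation, camera with the preset correlation found 5 of 5 lists of 25 genes shifted by 0.5 and called 0 of 20 unshifted lists. With an estimated correlation it found 0 of the 5 and called 0 of the 20. Members of these lists varied independently, so false calls in lists whose members vary together were not tested. The window scan found the 1 planted shift of 60 genes in 28332 simulated genes, and without a planted shift 0 windows passed.

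The alternatives tried were quantile normalization, median centring, another or no filter on dim rows, limma-trend with robust eBayes, the mean of all rows of a gene, the replicate number as a block, leaving out each array in turn, a stricter threshold, limma treat, a test of every row, an estimated correlation, and windows of 25 and 100 genes. A test of protein-coding genes alone, a test of every row with limma-trend and robust eBayes, and 2 alternatives for array similarity were added after the data were seen.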

Results

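NCI-H1299 is an established human cell line of non-small cell lung cancer, and NCI-H1299/CDDP is labelled as its cisplatin-resistant counterpart. Cisplatin is a platinum drug that forms adducts and crosslinks in DNA. The 4 arrays held 2 samples of each line, and the comparison asks which transcripts differ between the resistant and the original cells. No sample is labelled as exposed to the drug at collection. Values are the deposited log2 signals, given as mean ± SD over the arrays of a group or as a difference, NCI-H1299/CDDP minus NCI-H1299, with its standard error (SE).

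The arrays of the resistant line resembled each other more than they resembled the arrays of the original line. Across tested genes, Pearson's r was 0.987 between both NCI-H1299/CDDP arrays and 0.984 between both NCI-H1299 arrays, against 0.966 to 0.971 between lines. Genes are not independent replicates, so these values carry no test. The first principal component held 63.9% of the variance and separated the lines. The median SD of a gene between arrays was 0.13 in NCI-H1299/CDDP and 0.14 in NCI-H1299, and the median difference over all tested genes was 0.04.

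In the resistant cells 701 genes were higher and 310 lower, out of 28565 tested with limma. Of these, 511 and 223 differed at least 2-fold. Among the genes that rose most were those of thrombospondin 1, a matrix glycoprotein, and transglutaminase 2, a protein-crosslinking enzyme. *THBS1* went from 6.74 ± 0.25 to 10.41 ± 0.06 (SD, n = 2), a 12.8-fold difference (log2 3.67, SE 0.18, adjusted p = 0.000978), and *TGM2* from 6.39 ± 0.14 to 9.92 ± 0.12, an 11.6-fold difference (log2 3.54, SE 0.17, adjusted p = 0.000978). *CTCFL*, a germline paralog of the chromatin protein CTCF, rose by 4.51 (SE 0.26, adjusted p = 0.00132). *IL13RA2*, an interleukin 13 receptor chain, was among the genes that fell most, from 8.28 ± 0.61 to 3.35 ± 0.56 (SD, n = 2), a difference of -4.93 (SE 0.35, adjusted p = 0.00241).

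Other genes among the 12 named for a rise, chosen by fitted difference, were the semaphorin and VEGF co-receptor *NRP1* (3.63), *FAM133A* (3.61), the chemerin receptor *CMKLR2* (3.52), the cAMP phosphodiesterase *PDE4B* (3.52), *PLPP4* (3.49), the co-stimulatory receptor *TNFRSF9* (3.45), the microtubule-associated *MAP1B* (3.38), the kinase *PLK2* (3.31) and the interleukin 7 receptor *IL7R* (3.28). Genes that fell with *IL13RA2* were *RFPL4AL1* (-3.73), the glycosyltransferase *GALNT13* (-3.71), *LIN7A* (-3.64), the protocadherin *PCDHB6* (-3.56), the coagulation inhibitor *TFPI* (-3.56), the guanine deaminase *GDA* (-3.54), *RFPL4A* (-3.54), the retinol-binding *RBP7* (-3.45), *QNG1* (-3.35), the ketone-body enzyme *OXCT1* (-3.34) and *TMEM62* (-3.15). For *NRP1*, *FAM133A*, *CMKLR2*, *PDE4B* and *IL7R* the original line lay in the negative-control range, as did the resistant line for *IL13RA2*, *GALNT13*, *LIN7A*, *PCDHB6*, *TFPI*, *GDA*, *RBP7*, *OXCT1* and *TMEM62*. Background shrinks the differences of these genes, so their order is uncertain. *RFPL4A* and *RFPL4AL1* are near-identical neighbours whose probes may not tell them apart, so their values are uncertain. A second row of *CTCFL* gave -0.13 and a second row of *QNG1* gave 0.06, so for both genes the difference rests on 1 of 2 rows. Rows of *NRP1* (3.63 and 1.26) and *OXCT1* (-3.34 and -0.78) shared their sign.

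Of these 24 genes, 23 were also called with any 1 array left out. The exception was *RFPL4A*, at adjusted p = 0.0657 without NCI-H1299 replicate 1, and it was not called without NCI-H1299 replicate 2 either. The total of 1011 called genes fell to 189 without NCI-H1299/CDDP replicate 1, 213 without NCI-H1299/CDDP replicate 2, 223 without NCI-H1299 replicate 1 and 357 without NCI-H1299 replicate 2.

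**Figure D1:**
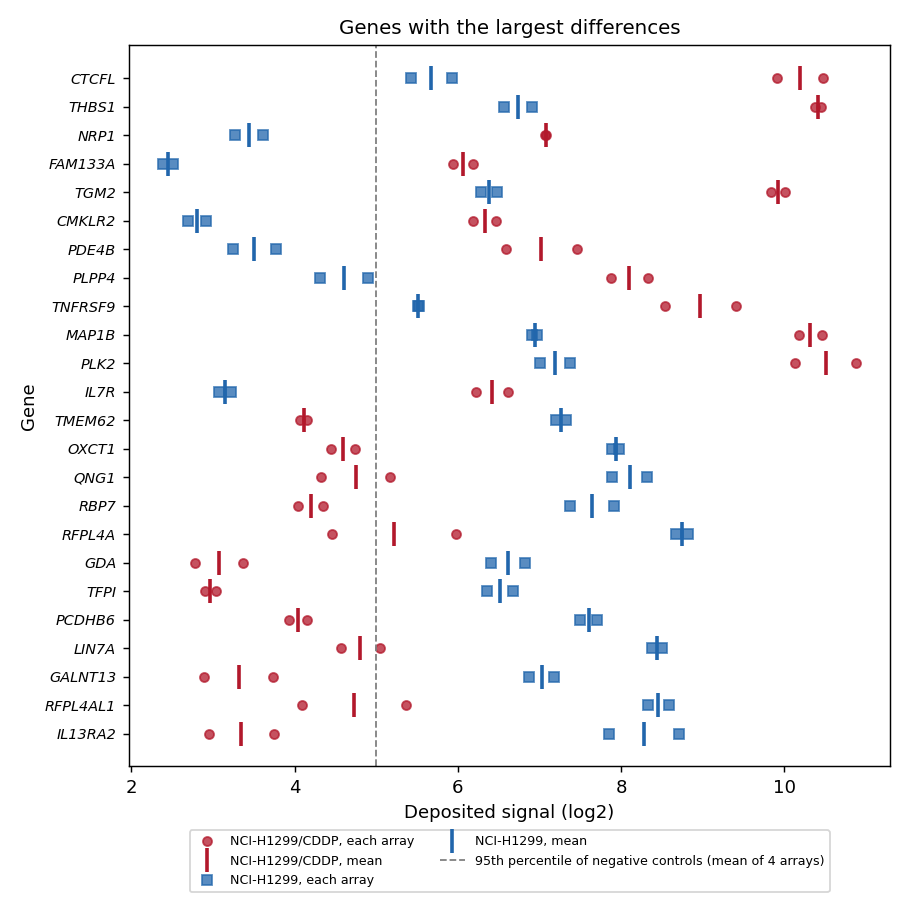
Deposited log2 signal (horizontal axis) of the 12 genes named for a rise and the 12 named for a fall in NCI-H1299/CDDP, with a point for each array, a bar for each group's mean and a dashed line at the mean 95th percentile of the negative controls. The arrays of both lines separate for each gene, as the rule that chose the genes required. For IL13RA2 the means are 3.35 in NCI-H1299/CDDP and 8.28 in NCI-H1299.

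Of the genes of nucleotide excision repair, the pathway that removes platinum adducts from DNA, 2 fell. *ERCC1*, a subunit of the repair nuclease, fell 3.04-fold, from 10.06 ± 0.05 to 8.46 ± 0.13 (SD, n = 2; difference -1.60, SE 0.17, adjusted p = 0.00662), and *ERCC2*, a helicase subunit, fell by 1.34 (SE 0.16, adjusted p = 0.0108). The other 24 of 26 measured members did not pass, with a median of 0.14 over all 26, and the list was not called by camera (adjusted p = 0.998). Adjusted over the list alone, 1 member was higher and 2 were lower. *ERCC4* (0.19) and *XPA* (-0.15) did not pass. *ERCC1* was called with 3 of the 4 arrays left out in turn, at adjusted p = 0.0541 without NCI-H1299/CDDP replicate 2, and *ERCC2* with none, at adjusted p between 0.0506 and 0.0844.

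Of 20 measured genes for uptake, efflux and binding of cisplatin or copper, 1 rose and 0 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.349). The efflux transporter *ABCC3* rose by 1.11 (SE 0.18, adjusted p = 0.0292), with the original line in the negative-control range, and it did not pass with any 1 array left out (adjusted p from 0.0607 to 0.152). The copper transporter *SLC31A1*, a route of platinum uptake, differed by 0.01 (SE 0.16), *ATP7A* by -0.24 and *ATP7B* by 0.38. *ABCB1* (-0.15), *ABCC1* (0.28), *ABCC2* (0.24) and the volume-regulated channel gene *LRRC8A* (0.56, adjusted p = 0.115) did not pass. *ABCG2* lay in the negative-control range in both lines.

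Of 30 measured Fanconi anaemia and homologous recombination genes, 2 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.998). *XRCC2* (1.17, SE 0.18) and *RAD51B* (0.85, SE 0.17) rose, and *REV3L*, a subunit of a translesion polymerase, fell by 0.84 (SE 0.16). Their adjusted p-values were 0.0245, 0.0453 and 0.0429, and none passed in a fit that left out an array, at adjusted p up to 0.201. A second row of *RAD51B* gave -0.20, and with the mean of its rows its adjusted p was 0.328. The median of the list was 0.04, and its direction was not resolved: camera gave lower (camera unadjusted p = 0.964) and fry gave higher. Of 7 measured mismatch repair genes, limma called 0, with 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.475); the smallest p-values were those of *EXO1* (0.65) and *PCNA* (0.43).

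Of 29 measured NRF2 targets and glutathione genes, 2 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0892). The glutathione transferase *GSTM3* rose 3.15-fold (log2 1.65, SE 0.18, adjusted p = 0.00860) and the thioredoxin reductase *TXNRD1* by 0.94 (SE 0.16, adjusted p = 0.0295), while malic enzyme *ME1* fell by 1.32 (SE 0.25, adjusted p = 0.0431). *GSTP1* (0.48, adjusted p = 0.175), *NFE2L2* (0.24) and *KEAP1* (-0.11) did not pass. Of 25 measured apoptosis genes, BCL2-family members, inhibitors, caspases and death receptors among them, 2 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.291). Both that rose are known to promote cell death, the BH3-only gene *PMAIP1* (1.58, SE 0.29) and the death receptor *TNFRSF10B* (0.96, SE 0.16). The third member, higher only when adjusted over the list alone, was *CFLAR* (0.81, limma adjusted p = 0.0304 over the list and 0.0701 over all genes). *BCL2* (0.31), *BCL2L1* (-0.36) and *MCL1* (0.00) did not pass. Each of the 5 called genes lost its call with at least 1 array left out, at adjusted p up to 0.178.

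Some interferon-stimulated and antigen presentation genes rose in the resistant cells. Of 33 measured interferon-stimulated genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.37. Among them were *SAMD9L* (1.94, SE 0.23), *IFIT2* (1.63, SE 0.18), *GBP1* (1.62, SE 0.17) and *IFIT1* (1.52, SE 0.16), the last at adjusted p = 0.00674; for *SAMD9L* and *GBP1* the original line lay in the negative-control range, which shrinks their differences. The list was called by camera (adjusted p = 0.000130; adjusted p = 0.526 with an estimated correlation). Of 20 measured antigen presentation genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone). These were the immunoproteasome subunit *PSMB9* (2.98, SE 0.19, adjusted p = 0.00190), the peptide transporter *TAP1* (1.06, SE 0.17) and the class I genes *HLA-B* (1.19), *HLA-E* (1.17), *HLA-C* (0.99) and *HLA-F* (0.86). HLA genes are closely related in sequence, and how the probes separate them is not known here. That list was called at adjusted p = 0.000351, with adjusted p = 0.526 with an estimated correlation.

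Of 23 measured NF-kappaB targets and cytokines, 5 rose and 0 fell, with a median of 0.19 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00537; adjusted p = 0.571 with an estimated correlation). The macrophage growth factor *CSF1* rose by 2.77 (SE 0.25), the NF-kappaB inhibitor *NFKBIA* by 1.81 (SE 0.19), *IL32* by 1.56 (SE 0.22) and the adhesion molecule *ICAM1* by 1.50 (SE 0.17), and *LIF* rose too (0.89). For *CSF1* the original line lay in the negative-control range, which shrinks its difference. Tested among protein-coding genes alone, an alternative chosen after the data were seen, this list had an adjusted p of 0.0531. *PSMB9*, *CSF1* and *NFKBIA* were called with any 1 array left out, and the other named genes of these 3 lists lost their call with at least 1, at adjusted p up to 0.218.

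Genes of developmental signalling, mesenchymal markers and matrix genes rose in part, while some markers fell. Of 32 measured Wnt, Notch and Hedgehog genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone). The Notch ligand *JAG1* rose 6.79-fold (log2 2.76, SE 0.26, adjusted p = 0.00513), its target *HES1* by 2.40 (SE 0.24), the Wnt receptor *FZD7* by 2.29 (SE 0.22) and the Wnt antagonist *DKK1* by 2.47 (SE 0.31). The other members that rose were *HHIP*, *GLI3*, *HEY1* and *HEY2*, with the original line in the negative-control range for *GLI3*. Camera called the list at adjusted p = 0.000317, with adjusted p = 0.526 with an estimated correlation. A second row of *DKK1* gave -0.11, and the gene was not called without NCI-H1299 replicate 1 (adjusted p = 0.0628) or without NCI-H1299 replicate 2. *HHIP*, *GLI3*, *HEY1* and *HEY2* lost their call with at least 1 array left out, at adjusted p up to 0.196, while *JAG1*, *HES1* and *FZD7* were called with any 1 left out.

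Of 22 measured mesenchymal markers, 5 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00835; adjusted p = 0.526 with an estimated correlation). Tenascin C (*TNC*, 2.54, SE 0.19), fibronectin (*FN1*, 2.49, SE 0.25), the transcription factor *PRRX1* (2.25, SE 0.20), N-cadherin (*CDH2*, 1.13, SE 0.19) and *SNAI2* (1.03) rose, and the receptor kinase *AXL* (-1.17, SE 0.19) and *LOX* (-0.93) fell. Vimentin (*VIM*) differed by 0.02 (SE 0.16), and E-cadherin (*CDH1*) lay in the negative-control range in both lines. Of 25 measured matrix genes, 4 rose and 0 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0432; adjusted p = 0.526 with an estimated correlation). Besides *THBS1* these were *EFEMP1* (2.23), *LAMB1* (1.66) and *TGFBI* (1.44). The original line lay in the negative-control range for *TNC* and *EFEMP1* and the resistant line for *LOX*, which shrinks their differences. Of 29 measured TGF-beta and BMP genes, 1 rose and 1 fell (3 and 1 adjusted over the list alone), *BMP4* by 1.38 (SE 0.23) and *TGFB1* by -1.13 (SE 0.16), with a median of 0.37 (camera adjusted p = 0.0188; adjusted p = 0.526 with an estimated correlation). Of 22 measured epithelial markers, desmoplakin (*DSP*, 1.61) rose and keratin 8 (*KRT8*, -0.94) fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.998). The mesenchymal, matrix and TGF-beta lists were not called among protein-coding genes alone (adjusted p = 0.0693, 0.268 and 0.134), the matrix list not without NCI-H1299 replicate 2 (0.0767) or NCI-H1299/CDDP replicate 1, and the TGF-beta list not without NCI-H1299/CDDP replicate 1 (0.111). Of the called genes in these lists, *TNC*, *FN1*, *PRRX1* and *THBS1* were called with any 1 array left out, and the others were not, at adjusted p up to 0.146 for *CDH2*, 0.151 for *AXL* and 0.206 for *SNAI2*.

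Several stress-response lists were called higher with the preset correlation. Of 30 measured unfolded protein response and ATF4 targets, 5 rose and 0 fell (13 and 1 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.000300; adjusted p = 0.526 with an estimated correlation). They were *ATF3* (1.89, SE 0.34), *HERPUD1* (1.47, SE 0.18), *DDIT3* (1.28, SE 0.26), *DNAJB9* (1.17, SE 0.17) and *SLC3A2* (1.02, SE 0.18). Of 8 measured metallothioneins, small proteins that bind zinc, copper and platinum, 1 rose over all genes tested and 7 rose adjusted over the list alone. *MT1X* rose 2.01-fold (log2 1.00, SE 0.16, adjusted p = 0.0281), and the median was 0.75, with all 8 differences above 0 (camera adjusted p = 5.02e-05; adjusted p = 0.526 with an estimated correlation). Metallothioneins are near-identical neighbours on chromosome 16, and the probes may read several of them.

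Of 31 measured hypoxia and glycolysis genes, *HK1* (1.16), *NDRG1* (0.97), *P4HA2* (0.90) and *BNIP3L* (0.89) rose and *GPI* (-1.02) fell, the same counts as adjusted over the list alone (camera adjusted p = 0.0276; adjusted p = 0.608 with an estimated correlation). Of 31 measured autophagy and lysosome genes 1 rose, *ATG14* (1.09), and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0456; adjusted p = 0.608 with an estimated correlation). Of 15 measured chaperones, *HSPB1* (1.35) and *DNAJB4* (0.98) rose and 0 fell, likewise adjusted over the list alone (camera adjusted p = 0.181). Among protein-coding genes alone the hypoxia and autophagy lists were not called (adjusted p = 0.203 and 0.283), nor were the hypoxia list without NCI-H1299/CDDP replicate 2 (0.347) or NCI-H1299 replicate 1 and the autophagy list without NCI-H1299/CDDP replicate 1 (0.186) or NCI-H1299 replicate 1. Each gene named for these 5 lists lost its call with at least 1 array left out, at adjusted p up to 0.195.

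Replication-dependent histone genes were the list with the smallest camera p, and it was called lower. Of 29 measured, 8 fell and 0 rose (14 and 2 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 2.15e-09; adjusted p = 0.526 with an estimated correlation). *H2BC14* fell 6.83-fold, from 8.68 ± 0.15 to 5.91 ± 0.17 (SD, n = 2; difference -2.77, SE 0.18, adjusted p = 0.00190), *H4C4* by 1.76 (SE 0.16), *H1-3* by 1.25 (SE 0.24) and *H4C1* by 1.19 (SE 0.20), the last with the resistant line in the negative-control range. *H2BC14* and *H4C4* were called with any 1 array left out, while *H1-3* and *H4C1* were not, at adjusted p up to 0.182. Of 39 measured DNA replication and G1/S genes, 1 rose, cyclin E2 (*CCNE2*, 1.01), and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.291). *CCNE2* lost its call with any array left out, at adjusted p up to 0.203. Of 35 measured mitosis genes limma called 0, with 6 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.846); the median was -0.03 and the mean 0.10. *HMMR* (0.80) and *MKI67* (-0.58) had the smallest p-values there.

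Cholesterol synthesis and cancer-testis genes were called lower as lists, with small shifts. Of 20 measured cholesterol genes limma called 0, with 0 higher and 2 lower at an unadjusted p under 0.05, and the median was -0.20 (camera adjusted p = 0.0207; adjusted p = 0.608 with an estimated correlation). The smallest p-values were those of *DHCR7*, at 7.93 in NCI-H1299/CDDP against 8.93 in NCI-H1299 (adjusted p = 0.0599), and *ACAT2* (-0.42). Of 17 measured cancer-testis genes limma called 0, with 0 higher and 2 lower at an unadjusted p under 0.05, and the median was -0.09 (camera adjusted p = 0.0276; adjusted p = 0.526 with an estimated correlation). *MAGEA4* (-0.60) and *MAGEA6* (-0.45), which are close relatives, had the smallest p-values. The germline gene *CTCFL*, which rose by 4.51 in the row used, is not among these 17, so the call covers the list's own members. The cholesterol list was not called without NCI-H1299/CDDP replicate 1 (adjusted p = 0.213), and the cancer-testis list not without NCI-H1299 replicate 2 (0.111), without NCI-H1299/CDDP replicate 1 or with no filter on dim rows (0.0992).

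Among receptor kinase and MAPK feedback genes, 4 of 33 measured rose and 2 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.922). The immediate-early genes *EGR1* and *IER3* each rose by 1.66, *HBEGF*, an EGF receptor ligand, by 1.47 and *MET* by 0.98, while neuregulin (*NRG1*) fell by 1.27 and *AXL* by 1.17. The list's median was 0.05, and its direction was not resolved: camera gave lower (camera unadjusted p = 0.837) and fry gave higher. Of 21 measured YAP and TAZ targets, *GADD45A* (1.79, SE 0.27) rose and *AXL* fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.922), with a median of -0.05 and a mean of 0.10. Of 18 measured stemness markers 2 rose, *EPAS1* (1.83) and *SOX9* (1.12), and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.259), and *CD44* (0.40) did not pass. Of 24 measured ferroptosis genes 2 rose, *GCH1* (1.36) and *SLC3A2* (1.02), and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.251). Of 27 measured ribosomal protein genes 0 rose and 1 fell, *RPS19* (-0.82), likewise adjusted over the list alone (camera adjusted p = 0.627), with a median of 0.03 and a mean of -0.01. Of 29 measured respiratory chain genes limma called 0, with 3 higher at an unadjusted p under 0.05, among them *NDUFA10* (0.74) and *NDUFA6* (0.51; camera adjusted p = 0.291). Each gene called in this paragraph lost its call with at least 1 array left out, at adjusted p up to 0.210.

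Markers of other cell types that a culture could hold were not called as lists. Of 11 measured fibroblast markers 1 rose, the microfibril protein *MFAP5* (1.69, SE 0.25, adjusted p = 0.0222; camera adjusted p = 0.524), and of 16 measured neuroendocrine markers 1 rose, *CHGB* (0.91, SE 0.18, adjusted p = 0.0477; camera adjusted p = 0.291); in both lists 0 fell, likewise adjusted over the list alone. Limma called 0 of 14 lung epithelial, 0 of 9 squamous and 0 of 17 blood and endothelial markers, with 1, 1 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.836, 0.627 and 0.913). The smallest p-values were those of *SFTPA1* (0.69) and *NKX2-1* (0.31), *S100A2* (0.55) and *KRT5* (0.26), and *ITGAM* (0.43) and *CD3E* (0.39), with the original line in the negative-control range for *SFTPA1*. *MFAP5* and *CHGB* lost their call with at least 1 array left out, at adjusted p up to 0.133 and 0.229.

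**Figure D2:**
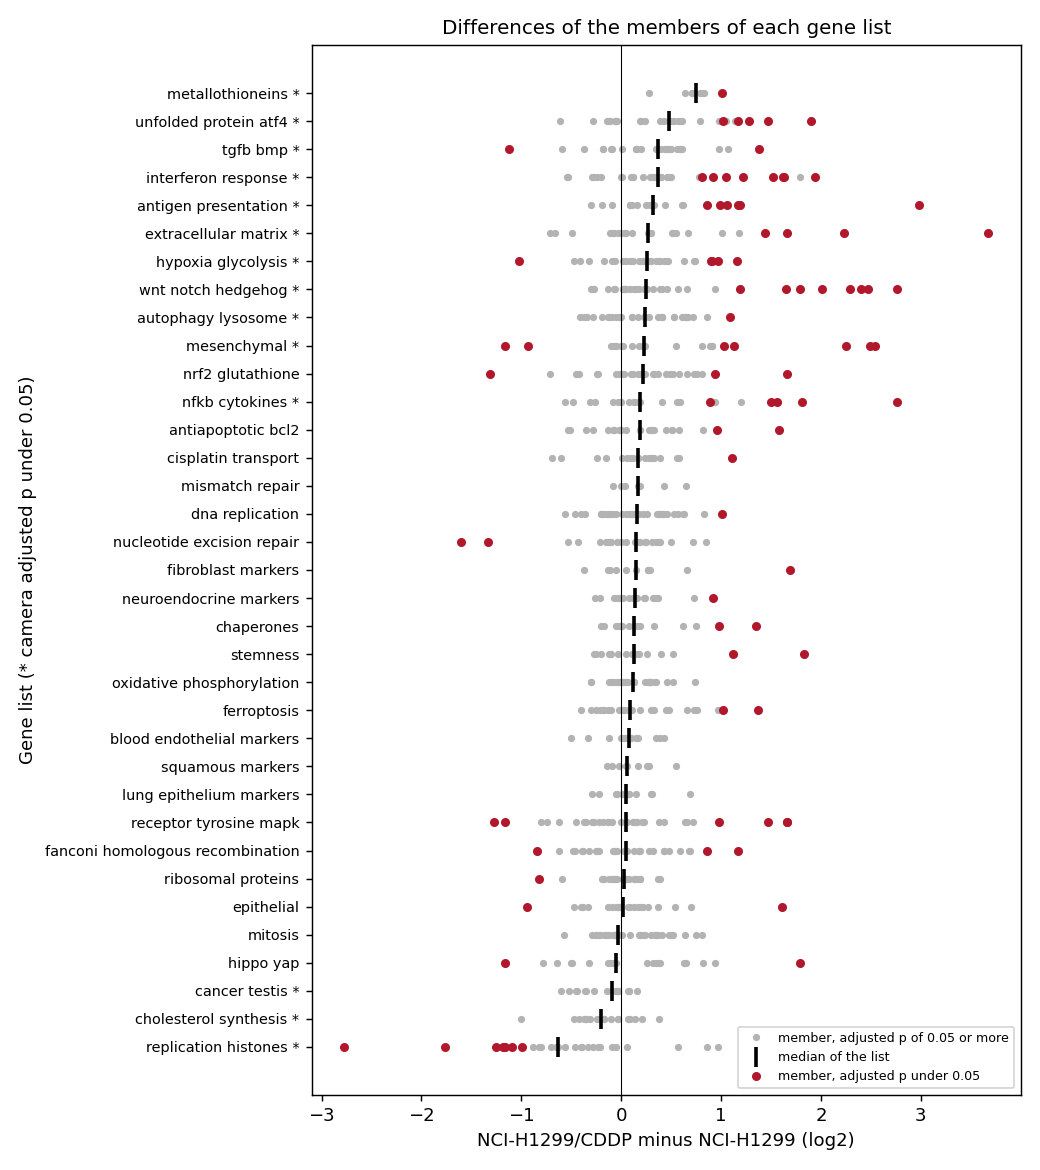
Differences between NCI-H1299/CDDP and NCI-H1299 (horizontal axis, log2) of the measured members of each of 35 gene lists, with red points for members at an adjusted p under 0.05, grey points for others and a bar at the list's median. Lists with an asterisk were called by camera with the preset correlation, and the medians run from -0.64 for the replication-dependent histones to 0.75 for the metallothioneins.

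In all, camera called 15 of the 36 lists, 12 higher and 3 lower. The 12 include the 1 list that is not reported here. With an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05, antigen presentation. Fry called 7 lists as moving in 1 direction and 32 as changing in either. The interferon, antigen presentation, Wnt, mesenchymal and matrix lists were among the 7, as were the chaperones (fry adjusted p = 0.0465), which camera did not call. Replication-dependent histones, metallothioneins, unfolded protein response and NF-kappaB targets were not, at fry adjusted p = 0.0876, 0.0741, 0.0630 and 0.0995. Nor were the TGF-beta, cholesterol, cancer-testis, hypoxia and autophagy lists (fry adjusted p from 0.103 to 0.270). Most lists hold protein-coding genes, whose median difference was 0.08 against 0.04 over all tested genes, and among protein-coding genes alone 8 lists were called. The filter at the 50th percentile left 10 lists called, ending the calls of the cancer-testis, TGF-beta, matrix, hypoxia and autophagy lists (adjusted p = 0.0686, 0.0754, 0.108, 0.0686 and 0.0641), and the mean of all rows ended those of the hypoxia (0.0533) and autophagy (0.0711) lists. Of the 94 called genes that the naming rule took, 30 were no longer called with no filter on dim rows. Quantile normalization ended the call of the autophagy list (adjusted p = 0.188) and of 6 of these genes, *HLA-E*, *CCNE2*, *RAD51B*, *AEN*, *SOX9* and *DDIT3* (adjusted p from 0.0520 to 0.0590), and the mean of all rows ended that of *P4HA2* (adjusted p = 0.113).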

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

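The test of every row was planned before the data were examined. Signals were seen in rows that the comparison of named genes did not use. When every row of the table was tested with limma, 14 rows that name no gene were higher in NCI-H1299/CDDP and 25 were lower. The largest differences among them were 3.61 and 3.42 (probes TC2100006500.hg.1 and TC0X00006723.hg.1) and -3.05 and -3.02 (probes TC1200006734.hg.1 and TC1400007571.hg.1). Of the rows that name several genes, 1 was higher (2.03, adjusted p = 0.0459) and 2 were lower (-4.66, adjusted p = 0.0176, and -5.11, adjusted p = 0.0460). In both of the lower rows the NCI-H1299/CDDP arrays lay between 2.43 and 4.10 and the NCI-H1299 arrays between 8.34 and 8.53. No gene is named for these rows, since they cannot say which of their genes differs, and no explanation for them was tested.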

How the results depend on the processing

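The test of protein-coding genes alone, the test of every row with limma-trend and robust eBayes, and the alternatives for array similarity were chosen after the data were seen. All 1011 called genes kept their sign in the refits by gene, wherever they were tested. No named gene or list called in either fit turned round. For the genes this was largely fixed in advance. Other filters, limma-trend, the replicate block and protein-coding genes alone keep each gene's fitted difference. A gene whose arrays separate by group cannot change sign when 1 array is left out. The counts of called genes did move. Against 701 genes higher and 310 lower, 368 and 152 were called with no filter on dim rows and 1224 and 566 with a filter at the 50th percentile. They were 1937 and 923 with limma-trend and robust eBayes, 138 and 54 at an adjusted p under 0.01, 93 and 56 with every row tested, and 1379 and 912 with every row tested with limma-trend and robust eBayes. Among protein-coding genes alone 1127 were higher and 414 lower. Against 511 and 223 genes changed at least 2-fold, limma treat against 1.2-fold called 284 and 124. Without each array in turn, 127 to 265 genes were higher and 57 to 92 lower, all of them at least 2-fold; the lone array left in a group is assumed to vary like the other group. Fewer arrays, fewer or more tests and a stricter threshold are the construction of these alternatives; for limma-trend the cause was not tested. Quantile normalization and median centring moved the median of all genes to at most 0.06. Of 94 named genes called, 34 were called with any 1 array left out, 31 with none, and 64 in each refit by gene that left out no array.

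Of 15 lists called, 9 were called with any 1 array left out, 10 with a filter at the 50th percentile, 8 among protein-coding genes alone and 0 with an estimated inter-gene correlation; the loss among protein-coding genes comes with a background of genes whose median is higher, and the cause of the others was not tested. The replicate numbers alone do not say whether same-numbered arrays were handled together. Across tested genes the deviations of same-numbered arrays correlated at 0.0159, which cannot settle it. The 95th percentile of the negative controls was higher in replicate 2 of both lines. It was 5.11 against 4.96 in NCI-H1299/CDDP and 5.03 against 4.89 in NCI-H1299. With the replicate block, 585 genes were higher and 263 lower, 769 of them among the 1011, and 14 lists were called, all but autophagy (adjusted p = 0.0525). Of the named genes, 8 were not called with it, HLA-E, RAD51B, REV3L, P4HA2, CHGB, AEN, RPS19 and DDIT3 (adjusted p from 0.0505 to 0.0653). The first principal component held 63.8% of the variance after quantile normalization and 59.1% with no filter on dim rows, against 63.9%; the cause was not tested. Regional shifts numbered 26 with windows of 50 genes, 22 with 25 and 23 with 100. They were not all the same stretches. Those from SCD5 to HERC3 and from NUDT1 to ZNF853 passed with windows of 50 alone. Chromosomes 5, 11 and 22 held stretches only with 25 and 100. With 100, the chromosome 19 stretches from ZNF254 to ZNF567 and from ZNF790 to DMWD fell within a lower stretch of 517 genes. A pseudocount other than 1 was not run, since the values were already on a log scale. Signal over background limits 106 higher genes with NCI-H1299 in the negative-control range, 60 lower genes with NCI-H1299/CDDP there and 35 called genes with both there.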

Other observations

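The scan for regional shifts was planned before the data were examined. The tests of GC-dependent background and of S phase, and the comparison of zinc finger genes, were chosen after the results they bear on were seen. In the resistant cells, the median difference of windows of 50 neighbouring genes passed the shuffled order in 26 stretches on 14 chromosomes, 15 of them higher and 11 lower. A stretch is given here by its outermost protein-coding genes, while the counts include genes of other kinds, some of them just outside those ends. Stretches were chosen by these same differences, so calls leaning to 1 side within them were largely fixed by the choice. They held 8.16% of the ordered genes and 24.1% of the called ones. Over all 28565 tested genes, 701 were called higher and 310 lower. On chromosome 7 the 99 genes from ALKBH4 to CPED1 held 13 called genes that were all higher, MET and LAMB1 among them (largest window median 0.41). On chromosome 1 the 97 genes from COL11A1 to CTTNBP2NL held 12 higher and 0 lower, CSF1 and GSTM3 among them (0.38), and on chromosome 8 the 107 genes from TUSC3 to ELP3 held 11 higher and 0 lower, TNFRSF10B and BNIP3L among them (0.31). On chromosome 6 the 119 genes from MARCKS to EYA4 held 11 lower and 2 higher (-0.34). Calls were mixed or few in some other stretches, with 3 higher and 5 lower from TUBA3D to RPRM, 2 and 2 from SCD5 to HERC3, 0 and 1 from LIMS2 to POTEE and 0 called from NUDT1 to ZNF853. The shuffled p of the windows with a median given was 0.0001 on chromosomes 7 and 1, the smallest that 10000 shuffles can give, 0.0016 on chromosome 8 and 0.0003 on chromosome 6. The shuffles moved genes and kept the differences of these arrays. This p thus compares neighbours with genes in random order and does not measure the spread between arrays. Related neighbouring genes or a GC-dependent background could also make neighbours alike, and the shuffles make no allowance for them. Several genes named for the lists are thus neighbours of other genes that moved the same way.

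Chromosome 19 held 5 of the stretches. From ZNF254 to ZNF567, 20 of 150 genes were lower and 0 higher, and from ZNF790 to DMWD 41 of 297 were lower and 1 higher, among them ERCC1, ERCC2, XRCC1, AXL, TGFB1, AKT2 and RPS19. Nearer its end, 7 genes were higher and 0 lower from LIM2 to DPRX and 25 higher and 2 lower, RFPL4A and RFPL4AL1, from ZNF865 to MZF1. Zinc finger genes with ZNF symbols, many of which encode transcriptional repressors, carried most of these higher calls. Relative to all coding genes, the 36 from LIM2 to DPRX had a median of 0.60, with 6 called higher and 0 lower, against -0.07 for the 15 other coding genes there, of which 0 were called. The 52 in the last stretch had a median of 0.67, with 20 called higher and 0 lower, against 0.12 for the 31 other coding genes beside them. In the fifth stretch, from CILP2 to ZNF98, the 24 ZNF genes had a median of 0.35 and the 5 other coding genes one of -0.11, with 0 called in either set. The 59 ZNF genes of chromosome 19 outside the stretches had a median of 0.28, with 5 called higher and 0 lower. The 681 other coding genes there had a median of -0.098, with 5 called higher and 4 lower. The 250 ZNF genes on other chromosomes had one of 0.18, with 9 called higher and 2 lower. The 15 between ZNF254 and ZNF567 had a median of -0.24, with 1 called lower, against -0.396 for the 86 other coding genes, with 19 called lower. The 45 between ZNF790 and DMWD had one of -0.39, with 0 called, near the -0.398 of the 187 others, with 39 called lower and 1 higher. ZNF genes are related in sequence, and this difference was not tested.

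The fall of ERCC1 and its neighbours between ZNF790 and DMWD was weighed against technical causes. The bootstrap intervals given here and below resampled the genes of a set, with the arrays fixed. They leave out the spread between arrays and treat neighbouring genes as independent, so they are narrower than the uncertainty of the comparison. If families of related genes read by shared probes were behind it, coding genes outside such families would stay near the median of all coding genes, but the 144 of them had a median of -0.609 (95% bootstrap interval -0.72 to -0.51), lower than the -0.23 of the 88 in families. If a background that depends on GC content were behind it, coding genes of the GC-rich chromosomes 17 and 22 would fall too. The lower of their medians was 0.0257 (interval 0.01 to 0.05). The 681 coding genes of chromosome 19 without ZNF symbols outside the stretches had a median of -0.098, a smaller fall. A GC effect on this chromosome as part of the cause was thus not excluded. Loss of a copy of this segment in the resistant line may explain the fall, a hypothesis that RNA levels cannot test and that DNA measurements would. Resistance, the selection of a clone and separate passage of the lines remain open together, since the design gives 1 resistant line.

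The lower histone genes lie mostly in a cluster on chromosome 6 that was itself among the stretches, from GPLD1 to H2AC11. A shift of the whole neighbourhood would lower its other coding genes by 0.4 or more, yet the 21 that are not histones had a median of 0.0808 (interval -0.14 to 0.24) against -0.74 for the 30 histones. Fewer cells in S phase could lower the DNA replication list, whose median relative to coding genes was 0.0720 (interval -0.08 to 0.17). That list mixes replication and G1/S genes and no cell-cycle phase was measured, so an S-phase difference was not excluded. The histone list's median of -0.637 (interval -0.88 to -0.33) also exceeded the largest fall of the background probes, -0.21. A change in the making or stability of these transcripts, most of which lack a poly(A) tail, may be involved, and cross-reading between near-identical histone genes could spread a change of some members over others; neither was tested.

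Metallothionein genes lie in a stretch on chromosome 16 from SNX20 to CFAP263 with 10 genes called higher, 5 of them metallothionein genes or pseudogenes, and 0 lower. The 53 coding genes there that are not metallothioneins had a median of 0.197 (interval 0.11 to 0.29), under the 0.5 that a regional shift as the whole cause would need and under the 0.63 of the 9 metallothioneins. A regional shift could therefore account for part of the rise. What lies behind the rest, including the shared sequence of these genes or a response to metals, was not tested.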
